A study of Homo sapiens with 4 samples.

How the data were processed

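RNA was sequenced from OVCAR8, an established human ovarian cancer cell line, in 2 groups of 2 libraries each. Cells of the group shCON carried a scrambled short hairpin and served as the negative control. Cells of the group shFAM49B carried short hairpins against FAM49B (also called CYRIB). Per the labels' protocols, lentiviral hairpin plasmids were delivered by lipofection and cells were collected 36 h later, whereas the series' design text speaks of a stable knockdown. Which of these holds, which hairpin sequence was used and whether cells were selected are not given in the sources used here. Libraries were made from total RNA with a NEBNext Ultra kit, per the labels' protocols. Group and replicate number were taken from the sample titles.

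The deposited table holds FPKM, reads per kilobase of gene scaled to sequencing depth, for 58735 genes in each of the 4 libraries, with gene coordinates, length and biotype, per the file headers. The aligner and the counting tool are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. The deposited table does not hold mouse genes: all 58735 identifiers are human Ensembl identifiers present in GENCODE release 29, and 58724 of them have the start and end of that annotation, so coordinates are given on the human build GRCh38. FPKM times gene length was a whole multiple of one step for 100% of values above 0 in each library (tolerance 0.001 of a step), so the reads behind each deposited FPKM value could be recovered. They came to 15639559 and 16875353 reads in shCON and to 16288871 and 16290200 in shFAM49B. The denominators implied by the deposited FPKM values were 1.08 and 1.10 times these totals in shCON and 0.941 and 0.919 times in shFAM49B, so a factor between libraries had been applied before deposit. In each library the denominator equalled, to within 3.06e-12%, the geometric mean of the 4 read totals times the library's median ratio to the geometric mean over the 20791 genes with reads in all 4 libraries, so the deposited values were already scaled by median ratios. That factor places the shFAM49B values higher, relative to shCON, than plain division by the library's reads would. At this depth 1 read in a gene of 1 kb equals 0.0541 to 0.0668 FPKM, and 3 reads equal 0.162 to 0.200 FPKM.

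Values were tested as deposited with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with empirical Bayes moderation along the mean-variance trend. Genes needed a mean of at least 1 FPKM over the 4 libraries, which left 13775 genes, 11400 of them protein coding. Tests were 2-sided and p-values were adjusted with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Every adjusted p of a gene comes from this limma fit. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes of low level, while folds are ratios of mean FPKM. With 2 libraries per group the fit had 2 residual degrees of freedom and borrowed 3.32 from the other genes. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within a group the recovered reads differed by a chi-square of 3.90 (shCON) and 3.48 (shFAM49B) per gene, over genes with at least 20 reads in the pair, against 48.9 to 56.1 between groups. Replicates therefore differed by more than counting noise and each was kept as 1 sample.

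Before the data were examined, 29 gene lists were fixed, of which 26 had at least 5 tested members. They were compared with the other tested genes by camera in limma, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists. The same test with a correlation estimated per list, and fry, which asks whether the members of a list move one way on balance without reference to other genes, stand beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, so a list can fail there even where its correlation is small. Calls of members are counted over all genes tested and adjusted over the list alone. The genes named in the text follow a rule also fixed before: FAM49B and its paralog FAM49A, the 10 largest log2 fold changes in each direction among protein-coding genes with a mean of at least 1 FPKM, an adjusted p under 0.05 and both libraries of one group above both of the other, and from each list the members with the smallest p, up to 4 for the MAPK lists and for lists past the set test and up to 2 for the others. Genes outside this rule are said to be so, and 1 gene that it would name is not reported here.

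The procedure was tested on simulated reads drawn from the means and depths of these libraries, with 200 genes changed by known folds. Limma on log2(FPKM + 1) recovered 0% of genes changed 1.25-fold (0 of 50), 26% of those changed 1.5-fold, 68% of those changed 2-fold and 90% of those changed 4-fold, and called 11 unchanged genes. Limma voom recovered 22%, 84%, 88% and 92% at these folds and called 1 unchanged gene. A single dispersion of 0.00277 was used for all genes, and far fewer genes changed than were called in the data. These rates therefore hold for the simulation only. Alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, a further scaling by median ratios over only the 13572 tested genes with reads in all 4 libraries, quantile normalization, rescaling to TPM, the variance model without trend and with robust moderation, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads, FPKM recomputed relative to the recovered reads of each library, and subtraction of a trend on GC content or on gene length within each library. Genes that share sequence with close copies (keratin paralogs, HSPA1A and HSPA1B, CSAG3, thymosin and ribosomal protein genes with pseudogenes) are uncertain, since the treatment of shared reads is not given. Use of strand in counting is not given either, so reads of overlapping genes on opposite strands cannot be assigned with certainty.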

Results

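The data are RNA-seq gene levels of the ovarian cancer cell line OVCAR8 with a scrambled hairpin (shCON, 2 libraries) or with hairpins against FAM49B (shFAM49B, 2 libraries), at 15639559 to 16875353 recovered reads per library. FAM49B encodes a protein that binds the GTPase RAC1 and restrains its signalling to the WAVE complex. The study's title concerns ovarian cancer cell growth and MAPK signalling, and the design implies one comparison, shFAM49B against shCON. Values are FPKM as deposited, given as mean ± SD (n = 2).

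FAM49B (ENSG00000153310, chromosome 8, 129839593 to 130017129 on the minus strand, GRCh38) stood at 7.41 and 7.60 FPKM in the shCON libraries and at 1.06 and 1.02 FPKM in the shFAM49B libraries. Its level was 7.51 ± 0.139 FPKM in shCON and 1.04 ± 0.0332 FPKM in shFAM49B, 7.21-fold lower. Together with FAM49B, 6 keratins, most of them of stratified epithelia, fell 11.1-fold to 26.3-fold, and 12 of 15 tested epithelial genes and 11 of 22 integrin and matrix adhesion genes were lower. All 39 tested genes of ribosomal proteins, 18 of 22 of cholesterol synthesis, 31 of 34 nuclear genes of the respiratory chain and 18 of 30 of DNA replication were higher in shFAM49B, mostly by less than 2-fold. None of these 6 lists passed camera with an estimated correlation (adjusted p = 0.401 to 0.576), a test that rests on 2 residual degrees of freedom. FAM49B fell by 2.06 on the log2(FPKM + 1) scale (SE 0.0807, limma adjusted p = 0.00054). Its paralog FAM49A (ENSG00000197872, chromosome 2) measured 2.87 ± 0.12 FPKM in shCON and 2.30 ± 0.115 FPKM in shFAM49B, a log2 fold change of -0.23 that did not pass (limma adjusted p = 0.0996). FAM49A did pass when values were rescaled to TPM (log2 fold change -0.51, adjusted p = 0.0223) or divided by the recovered reads (-0.39, adjusted p = 0.0248).

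**Figure D1:**
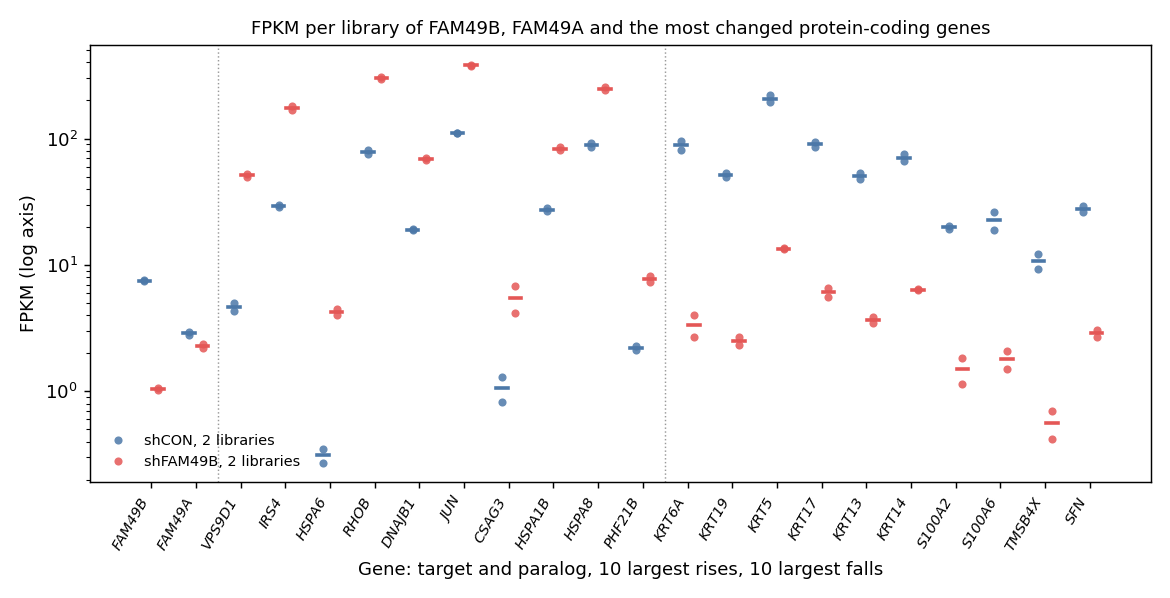
FPKM on a log axis of FAM49B, its paralog FAM49A and the 10 largest rises and falls among protein-coding genes, with 1 point per library and a bar at the mean of each group of 2 libraries. FAM49B lies at 7.41 and 7.60 FPKM in shCON and at 1.06 and 1.02 FPKM in shFAM49B, and KRT5 drops from 207 ± 18.0 to 13.5 ± 0.221 FPKM.

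The largest rise among protein-coding genes on the log2(FPKM + 1) scale was that of VPS9D1, which encodes a VPS9-domain protein, from 4.68 ± 0.525 to 51.2 ± 1.59 FPKM (10.9-fold, log2 fold change 3.20, adjusted p = 0.000166). IRS4, an adaptor of insulin receptor signalling, rose 5.98-fold, from 29.3 ± 0.745 to 175 ± 8.62 FPKM. Chaperone genes made up 4 of the 10 genes: HSPA6 rose from 0.312 ± 0.054 to 4.23 ± 0.349 FPKM (13.6-fold, a larger ratio than that of VPS9D1), DNAJB1 from 19.0 ± 0.318 to 69.0 ± 2.54, HSPA1B from 27.4 ± 1.14 to 83.4 ± 2.42 and HSPA8 from 89.0 ± 4.27 to 248 ± 8.91. JUN, a subunit of the AP-1 transcription factor, rose 3.43-fold, from 111 ± 0.971 to 380.0 ± 7.19 FPKM. RHOB, a small GTPase, rose 3.85-fold to 302 ± 8.09 FPKM. The remaining genes were CSAG3, a cancer-testis antigen, which rose 5.16-fold to 5.47 ± 1.86 FPKM, and PHF21B, which rose 3.49-fold to 7.72 ± 0.628 FPKM. Adjusted p of these 10 genes in limma ran from 0.000166 to 0.00514. Overlap with other tested genes was looked up for FAM49B, FAM49A and the 10 largest changes in each direction, 22 genes in all, of which 4 had one, and the overlapping genes are named only for that. VPS9D1-AS1, on the strand opposite VPS9D1, fell from 24.7 ± 0.279 to 17.7 ± 1.32 FPKM while VPS9D1 rose, and ZNF276, also opposite, did not pass (log2 fold change -0.06, adjusted p = 0.551). IRS4 overlaps AL035425.1 on the opposite strand and AL035425.2 on its own, which rose by log2 fold changes of 0.67 and 1.20. TECR, opposite DNAJB1, rose from 23.4 ± 0.17 to 38.5 ± 3.57 FPKM, and the small nucleolar RNA SNORD14E, on the strand of HSPA8, was at 0 in both shCON libraries and at 7.73 ± 4.26 FPKM in shFAM49B.

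Keratins made up 6 of the 10 largest falls. KRT6A fell from 88.9 ± 10.2 to 3.38 ± 0.935 FPKM (26.3-fold), KRT19 from 51.6 ± 2.71 to 2.52 ± 0.283 (20.5-fold) and KRT5 from 207 ± 18.0 to 13.5 ± 0.221 (15.4-fold). KRT17, KRT13 and KRT14 fell 14.7-fold, 13.7-fold and 11.1-fold. KRT5 and KRT14 form the filaments of basal cells of stratified epithelia, and KRT6A and KRT17 are keratins of activated and appendage epithelium. SFN, the epithelial 14-3-3 sigma protein, fell 9.65-fold to 2.88 ± 0.226 FPKM, and the calcium-binding proteins S100A2 and S100A6 fell 13.3-fold and 12.5-fold. TMSB4X, which encodes the actin-binding thymosin beta 4, fell from 10.8 ± 2.00 to 0.563 ± 0.201 FPKM. Limma adjusted p of these 10 falls ran from 0.000166 to 0.00115. The 7.21-fold lower FAM49B and the 15.4-fold lower KRT5 were measured in the same libraries.

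Of the 13775 genes tested, 3642 were higher and 2170 lower in shFAM49B at a limma adjusted p under 0.05, together 42.2% of genes, and 425 of them (171 higher, 254 lower) differed at least 2-fold. Both libraries of one group lay above both of the other for 74.7% of genes, where chance gives 33.3%. The split of calls depended on the scaling. The deposited values had been scaled by median ratios over 20791 genes with reads in all libraries. Of the called genes 62.7% were higher as deposited, against 52.5% after a further scaling by median ratios over the 13572 of these genes that were tested (2926 higher, 2647 lower), 52.0% after quantile normalization (2647 higher, 2446 lower), 26.8% as TPM (1597 higher, 4362 lower) and 29.2% relative to recovered reads (1722 higher, 4173 lower). Rescaling to TPM moved the log2 fold changes of genes by a median of -0.24 and the recomputed FPKM by a median of -0.19, so small rises and falls are relative to the scaling chosen.

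**Figure D2:**
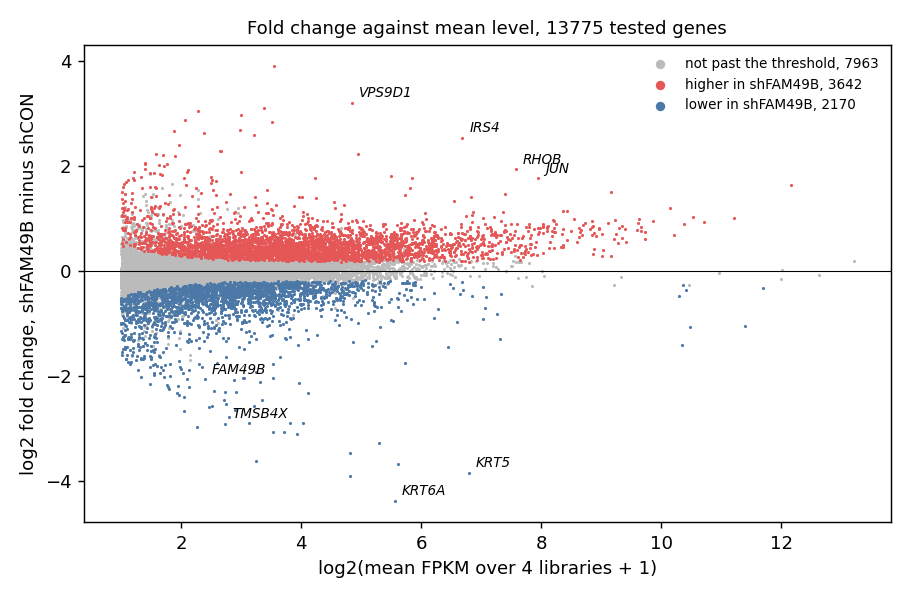
Log2 fold change (shFAM49B minus shCON, on log2(FPKM + 1)) against log2 of the mean FPKM over 4 libraries plus 1, with 1 point per tested gene. The 3642 genes called higher and the 2170 called lower are coloured, and KRT6A lies lowest, at -4.37.

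Of 13 tested ERK output genes, transcripts that report activity of the MAPK pathway, 7 fell and 2 rose in shFAM49B, over all genes tested and adjusted over the list alone, and 4 did not pass. The median log2 fold change of the list was -0.27 and its mean -0.30 (camera adjusted p = 0.0403, fry adjusted p = 0.0149), and camera did not pass it with an estimated correlation (adjusted p = 0.409). IER3, an early response gene of cell survival, fell from 12.03 ± 0.871 to 6.74 ± 0.288 FPKM, CCND1, which encodes cyclin D1, from 32.4 ± 3.19 to 18.3 ± 0.0637, and SPRED2, a feedback inhibitor of RAS signalling, from 6.43 ± 0.0402 to 3.76 ± 0.237. MYC rose 1.5-fold, from 80.3 ± 4.14 to 120.5 ± 0.674 FPKM. The list's camera call was also lost with a filter at 5 FPKM (adjusted p = 0.106), after quantile normalization (0.0701), as TPM (0.083), relative to recovered reads (0.0735), without shCON replicate 2 (0.0688) and without shFAM49B replicate 1 (0.0569), each with a negative median. The stratified epithelial keratins KRT5 and KRT14 were 15.4-fold and 11.1-fold lower in the same libraries.

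Other MAPK genes moved in both directions. Of 15 immediate early genes, 5 rose and 5 fell, counted over all genes and adjusted over the list alone: JUN rose 3.43-fold and KLF6 2.29-fold, from 9.37 ± 0.0236 to 21.5 ± 0.613 FPKM, while EGR1 fell 3.37-fold, from 5.77 ± 0.578 to 1.71 ± 0.283, and MCL1, an anti-apoptotic BCL2 relative, fell 1.63-fold. The list's median was 0.01 and its mean 0.07, camera placed it lower (adjusted p = 0.832) and fry higher (adjusted p = 0.222), and the median turned negative under 8 alternatives, all 4 scalings among them. Of 31 MAPK cascade components, 8 rose (9 adjusted over the list alone) and 7 fell on both counts, among them the kinases MAP2K7 (1.82-fold higher), ARAF (1.56-fold higher) and MAP3K1 (1.47-fold higher). The cascade list had a median of -0.06 and a mean of 0.02 (camera downward, adjusted p = 0.4554, fry upward, adjusted p = 0.388). Of 18 receptors and ligands upstream of MAPK, 4 rose and 6 fell, also adjusted over the list alone. AREG, an EGFR ligand, fell 13.3-fold from 5.35 ± 0.00773 to 0.403 ± 0.29 FPKM and VEGFA fell 1.86-fold, while PDGFA rose 1.90-fold and the receptor KIT rose 1.93-fold (list median -0.07, camera adjusted p = 0.358, fry adjusted p = 0.0156). Its median was 0.17 when only genes of at least 5 FPKM were kept. AREG fell in the libraries in which KRT5 was 15.4-fold lower.

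Epithelial adhesion genes had the lowest median of the 26 lists. Of 15 tested epithelial genes, 12 fell and 3 did not pass, over all genes and adjusted over the list alone, with a median log2 fold change of -1.35 (camera adjusted p = 6.37e-08, fry adjusted p = 0.00573, adjusted p = 0.401 with an estimated correlation). The size of that median depended on how low values were treated: it was -0.58 without a filter, -2.59 with a pseudocount of 0.1, -2.32 as TPM and -2.84 with voom, each past the threshold, and the list had too few genes for a test with a filter at 5 FPKM. Besides KRT19, the desmosomal plakophilin PKP3 fell from 4.63 ± 0.026 to 0.401 ± 0.0178 FPKM, CDH1, which encodes E-cadherin, from 3.60 ± 0.123 to 0.352 ± 0.0997, and the membrane protease ST14 from 3.52 ± 0.587 to 0.296 ± 0.00564. Of 22 integrin and matrix adhesion genes, 11 fell and 3 rose (11 and 4 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.00159, adjusted p = 0.576 with an estimated correlation). That median was -0.54 as TPM and -0.44 relative to recovered reads. LAMB3 and ITGB4, laminin and integrin chains of hemidesmosomes, fell 6.02-fold and 8.25-fold, ITGA3 fell 2.92-fold and ITGAV 2.11-fold. Of 18 mesenchymal genes, 5 rose and 3 fell on both counts: VIM, which encodes vimentin, rose 1.51-fold to 126 ± 3.53 FPKM and the metalloprotease MMP2 fell 1.95-fold. The mesenchymal median of 0.07, mean of -0.01 and the directions of camera (down, adjusted p = 0.964) and fry (up, adjusted p = 0.319) differed in sign, and the median was -0.17 as TPM and -0.14 relative to recovered reads.

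Among transcriptional targets of YAP with TEAD and of TGF-beta with SMAD, more fell than rose. Of 16 YAP and TEAD targets, 7 fell, 1 rose and 8 did not pass, also adjusted over the list alone (median -0.16, camera adjusted p = 0.0132, adjusted p = 0.409 with an estimated correlation). The YAP and TEAD median was -0.42 as TPM and -0.35 relative to recovered reads. F3, which encodes tissue factor, fell 9.94-fold from 10.2 ± 0.0355 to 1.02 ± 0.131 FPKM, AJUBA fell 1.83-fold, FJX1 1.82-fold and CRIM1 1.33-fold. CRIM1 did not pass without shCON replicate 1 (log2 fold change -0.34, adjusted p = 0.0693). Of 15 TGF-beta and SMAD targets, 10 fell, 3 rose and 2 did not pass, also adjusted over the list alone (median -0.46, camera adjusted p = 0.00249, adjusted p = 0.409 with an estimated correlation). Their median was -0.74 as TPM and -0.65 relative to recovered reads. SMAD7 and SKIL, feedback inhibitors of the pathway, fell 2.67-fold and 3.03-fold and JUNB fell 1.59-fold, while ID3, which BMP signalling also induces, rose from 70.6 ± 9.04 to 131 ± 1.16 FPKM. Both lists were measured in libraries with 15.4-fold lower KRT5.

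Among genes of DNA replication and mitosis, more rose than fell in shFAM49B. Of 30 replication and G1/S genes, 18 rose and 12 did not pass, also adjusted over the list alone (median 0.26, camera adjusted p = 0.000355, adjusted p = 0.552 with an estimated correlation). CDT1, which loads the replicative helicase, rose 2.19-fold from 102 ± 3.41 to 224 ± 19.9 FPKM, the transcription factor E2F1 rose 1.73-fold, and the helicase subunits MCM5 and MCM7 rose 1.78-fold and 1.75-fold. Of 29 G2/M genes, 18 rose and 3 fell on both counts (median 0.35, camera adjusted p = 0.0132, adjusted p = 0.409 with an estimated correlation), among them CDC20 (1.66-fold higher), KIF20A (1.67-fold higher), TPX2 (1.46-fold higher) and the kinase AURKB (1.45-fold higher). After quantile normalization neither list passed (adjusted p = 0.261 and 0.437), and the mitotic list did not pass with a filter at 5 FPKM (0.117). Their medians stayed above 0 under every scaling and were 0.03 and 0.11 as TPM. KRT5 was 15.4-fold lower in the same shFAM49B libraries.

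Among targets of p53 and regulators of apoptosis, more fell than rose. Of 21 p53 targets, 7 fell (8 adjusted over the list alone) and 3 rose on both counts (median -0.14, camera adjusted p = 0.0403, adjusted p = 0.409 with an estimated correlation). The stress sensor SESN2 fell 2.61-fold from 53.6 ± 0.593 to 20.5 ± 0.12 FPKM, PHLDA3 fell 3.54-fold, the ribonucleotide reductase subunit RRM2B 1.65-fold and MDM2, which degrades p53, 1.73-fold. The p53 list did not pass without a filter (adjusted p = 0.0979), with one at 5 FPKM (0.109) or without shFAM49B replicate 1 (0.0569). The median of the p53 list was -0.0021 with a filter at 5 FPKM, -0.38 as TPM and -0.35 relative to recovered reads. Of 18 apoptosis regulators, 6 fell and 1 rose, also adjusted over the list alone (median -0.18, camera adjusted p = 0.00551, adjusted p = 0.409 with an estimated correlation). The apoptosis median was -0.44 as TPM and -0.35 relative to recovered reads. Falling members act on both sides: MCL1 and BIRC2 restrain cell death and fell 1.63-fold and 1.53-fold, while PMAIP1 and CASP8 promote it and fell 1.67-fold and 1.88-fold. The same libraries held 15.4-fold less KRT5.

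**Figure D3:**
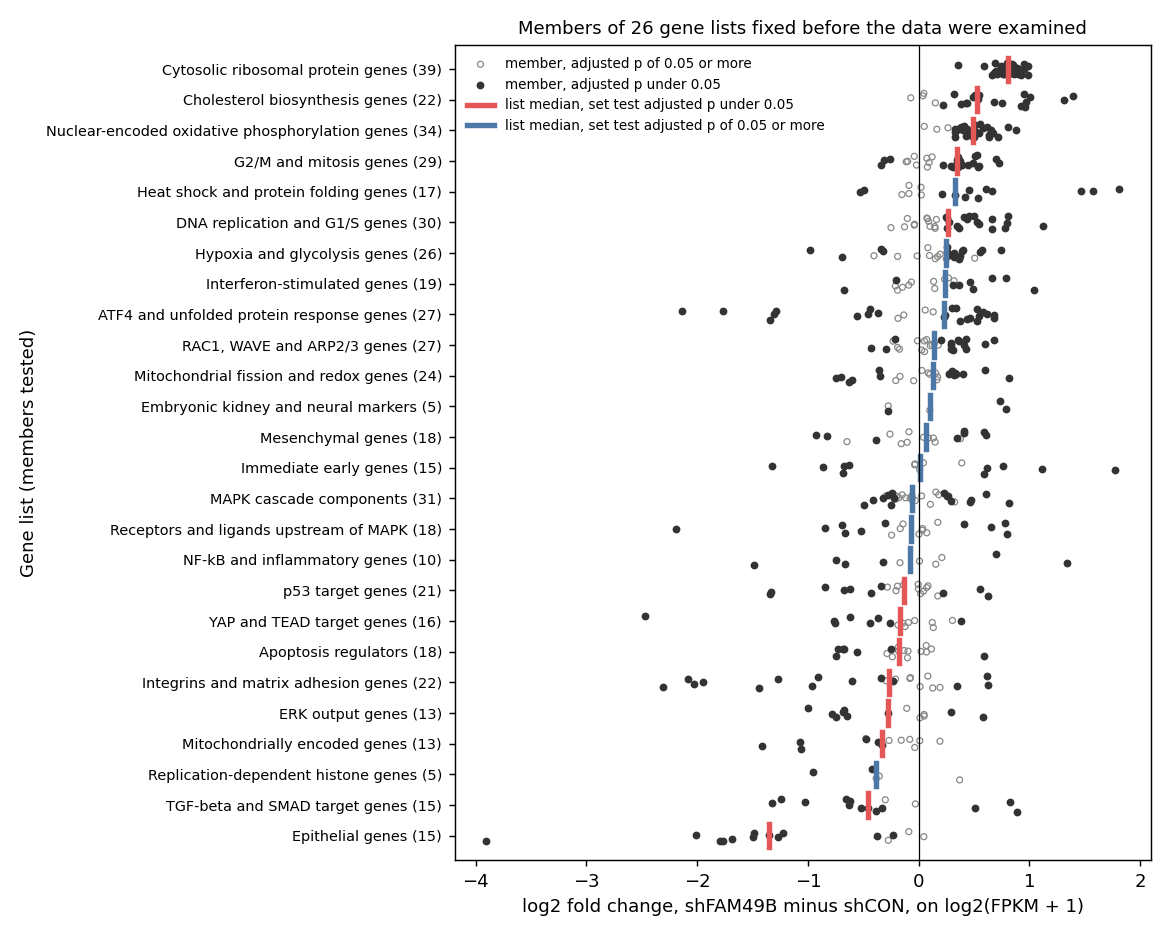
Log2 fold change (shFAM49B minus shCON, on log2(FPKM + 1)) of the members of 26 gene lists, with filled points for members past the limma threshold and a bar at each list's median, red where the camera adjusted p was under 0.05. Medians run from -1.35 for epithelial genes to 0.81 for cytosolic ribosomal protein genes.

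Most tested genes of cholesterol synthesis and most nuclear genes of the respiratory chain rose. Of 22 cholesterol biosynthesis genes, 18 rose and 4 did not pass, also adjusted over the list alone (median 0.52, camera adjusted p = 1.4e-06, fry adjusted p = 0.00373, adjusted p = 0.401 with an estimated correlation). INSIG1, a sterol sensor, rose 2.79-fold from 9.49 ± 0.243 to 26.5 ± 0.214 FPKM, and the enzymes MSMO1, HMGCS1 and FDFT1 rose 2.6-fold, 2.09-fold and 1.99-fold. Of 34 nuclear genes of oxidative phosphorylation, 31 rose and 3 did not pass, also adjusted over the list alone (median 0.49, camera adjusted p = 5.08e-09, adjusted p = 0.409 with an estimated correlation). UQCRC2 of complex III rose 1.86-fold, NDUFV1 of complex I 1.66-fold and the ATP synthase subunits ATP5F1A and ATP5F1B 1.57-fold and 1.58-fold, though ATP5F1B had a log2 fold change of -0.01 after quantile normalization. Both medians stayed above 0 under every scaling (0.33 to 0.50 and 0.27 to 0.42). In these libraries KRT5 was 15.4-fold lower.

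Of 13 protein-coding genes of the mitochondrial genome, 6 fell and 7 did not pass, also adjusted over the list alone (median -0.33, -0.15 without shCON replicate 1, camera adjusted p = 0.00199, adjusted p = 0.576 with an estimated correlation, fry adjusted p = 0.0588). MT-ND2 fell 2.67-fold from 1884 ± 133 to 706 ± 17.6 FPKM, MT-ND1 fell 2.11-fold, MT-CYB 2.08-fold and MT-ND5 1.40-fold. MT-ND5 did not pass without shCON replicate 1, shFAM49B replicate 1 or shFAM49B replicate 2 (adjusted p = 0.0509, 0.129 and 0.116), and neither MT-ND5, MT-CYB nor the list passed without a filter on low values (adjusted p = 0.231, 0.122 and 0.0563). Both mitochondrial ribosomal RNA genes rose (median log2 fold change 1.57). Mitochondrial ribosomal RNA took 0.412 ± 0.0497% of reads in shCON and 1.08 ± 0.011% in shFAM49B, and all mitochondrial genes took 5.02 ± 0.357% and 4.59 ± 0.048%. Of 24 genes of mitochondrial fission and redox balance, 8 rose and 6 fell on both counts, among them the lipid peroxidase GPX4 (1.77-fold higher) and heme oxygenase HMOX1 (1.79-fold lower). Their median of 0.13 (camera upward, adjusted p = 0.946, fry downward, adjusted p = 0.957) was -0.08 after quantile normalization, -0.11 as TPM and -0.09 relative to recovered reads. Of 26 hypoxia and glycolysis genes, 12 rose and 4 fell on both counts (median 0.25, camera adjusted p = 0.152, adjusted p = 0.00876 without a filter), among them PGK1 (1.68-fold higher) and PFKP (1.51-fold higher), and their median lay at 0.00 after quantile normalization.

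All 39 cytosolic ribosomal protein genes rose, also adjusted over the list alone (median 0.81, camera adjusted p = 7.26e-16, adjusted p = 0.409 with an estimated correlation). RPL4 rose 1.94-fold from 312 ± 6.25 to 605 ± 14.3 FPKM, RPS4X 1.93-fold, RPL3 1.89-fold and RPS9 1.79-fold. The median stayed positive under every scaling, lowest at 0.26 after quantile normalization, and the 50 most abundant genes took 12.7 ± 0.293% of reads in shCON and 15.7 ± 0.186% in shFAM49B. Of 17 heat shock and folding genes, 10 rose and 2 fell on both counts, with a median of 0.33 (camera adjusted p = 0.0534, adjusted p = 0.576 with an estimated correlation, fry adjusted p = 0.0149). By limma p the first members of this list were DNAJB1 (3.63-fold higher) and HSPA1B (3.04-fold higher). Camera passed the heat shock list without a filter (adjusted p = 0.00564), after the further scaling by median ratios (0.0488), as TPM (0.0304), relative to recovered reads (0.0288), with voom (0.0116) and with the GC trend subtracted (0.0156). Its median was 0.34 without shCON replicate 1, 0.30 without shFAM49B replicate 2 and -0.08 after quantile normalization. Of 27 genes of ATF4 and the unfolded protein response, 14 rose and 9 fell on both counts. SESN2 fell 2.61-fold and CHAC1, a glutathione-degrading ATF4 target, fell 5.10-fold from 24.6 ± 1.55 to 4.83 ± 0.514 FPKM. The list's median was 0.23 but its mean -0.12 and its camera direction downward (adjusted p = 0.964), and after quantile normalization the median was -0.12 and the list passed (adjusted p = 0.0300).

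Of 27 actin-regulating genes of RAC1, the partner of the FAM49B protein, and of WAVE and ARP2/3, 12 rose, 3 fell and 12 did not pass on both counts (median 0.14, camera adjusted p = 0.152, fry adjusted p = 0.0149), among them RHOA (1.6-fold higher, 279 ± 8.10 FPKM) and the WAVE subunit WASF2 (1.54-fold higher). The list passed without a filter (adjusted p = 0.00229), but its median was -0.08 as TPM and -0.05 relative to recovered reads. Of 19 interferon-stimulated genes, 7 rose and 2 fell on both counts (median 0.23, camera adjusted p = 0.204, fry adjusted p = 0.0187), among them OASL (2.16-fold higher) and IFIT1 (1.76-fold higher). Of 10 NF-kB and inflammatory genes, 2 rose and 4 fell on both counts (median -0.08, camera adjusted p = 0.4552, and 0.15 with a filter at 5 FPKM), with the chemokine CCL5 2.56-fold higher at 133 ± 4.86 FPKM and PTGS2, which encodes COX-2, 5.95-fold lower. That list passed without a filter (adjusted p = 0.034).

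Markers of other cell types were mostly low. The median of 18 leukocyte markers was at most 0.062 FPKM in any library, and that of 11 endothelial markers at most 0.0585 FPKM. Of 14 fibroblast and stromal markers 4 had a mean of at least 1 FPKM, with FBLN1, picked after its values were seen, highest at up to 33.1 FPKM. These 3 lists had fewer than 5 tested members and no set test. Of 5 tested embryonic kidney and neural markers, 2 rose and 1 fell on both counts (median 0.10, camera adjusted p = 0.737, fry adjusted p = 0.0246). The neurofilaments NEFL and NEFM rose 1.75-fold and 1.68-fold, to 45.2 ± 1.06 and 46.7 ± 1.59 FPKM, and the list's median was -0.08 as TPM, -0.05 relative to recovered reads and -0.01 without a filter. Of 5 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 2 fell on both counts (median -0.38, camera adjusted p = 0.136). They were HIST1H2BD (2.81-fold lower) and HIST1H2BK (1.37-fold lower), of which HIST1H2BK did not pass without a filter (adjusted p = 0.135), without the trend in the variance (0.064), or when shCON replicate 2 (0.074), shFAM49B replicate 1 (0.139) or shFAM49B replicate 2 (0.131) was left out. The histone list passed without a filter (adjusted p = 0.00164) and without shCON replicate 1 (adjusted p = 0.0173).

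In all, camera with the preset correlation called 13 of the 26 lists, 5 higher and 8 lower, and 12 of these 13 also passed fry. With an estimated correlation camera called 0 lists after Benjamini-Hochberg adjustment and 2 at an unadjusted p under 0.05 (cholesterol biosynthesis, p = 0.0294, and epithelial genes, p = 0.0308), while fry, which makes no comparison with other genes, passed 18 of the 26. That form of camera rests on 2 residual degrees of freedom. For cholesterol biosynthesis the estimated correlation was -0.044, below the preset 0.01, yet the camera p went from 2.16e-07 to 0.0294. Among called lists it was 0.905 for mitochondrially encoded, 0.505 for ribosomal protein, 0.337 for integrin, 0.286 for oxidative phosphorylation and 0.213 for replication genes. For the other called lists it ran from -0.044 to 0.089. Where the estimate lies far above 0.01, camera p with the preset may be too small. Failing camera with an estimated correlation therefore cannot tell correlation between genes from few degrees of freedom. Each list was measured in libraries in which 32 further stratified epithelial markers, chosen after the data were seen, had a median log2 ratio of FPKM of -2.60 in shFAM49B against shCON.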

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

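Limma voom on recovered reads, FPKM relative to recovered reads and the GC and length trends were chosen after the data were seen, and the other tests were planned. FAM49B kept its fall under each alternative that tested it (log2 fold change -1.96 with the GC trend subtracted to -2.85 with voom, -2.04 to -2.08 with 1 library left out, limma adjusted p at most 0.0181), and was below the filter at 5 FPKM. The planned count test applied only if raw counts were deposited and was not run, since FPKM were deposited. The recovered reads were tested with limma voom instead. Of the other 99 genes that the naming rule gives, the only one to change sign under any alternative was ATP5F1B, at -0.0085 after quantile normalization. In simulation at this depth limma on log2(FPKM + 1) recovered 26% of 1.5-fold and 68% of 2-fold changes and voom 84% and 88%, so most misses in the simulation follow the method. The simulation changed 200 genes, whereas 5812 of 13775 genes were called in the data, so these rates do not carry over to the data. What depth limits was not split by level.

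Genes higher numbered 2185 without a filter, 1597 as TPM and 1722 relative to recovered reads. Genes lower numbered 1378 without a filter, 1322 at 5 FPKM, 4362 as TPM and 4173 relative to recovered reads. Genes changed at least 2-fold numbered 720 with a pseudocount of 0.1, 152 at 5 FPKM, 862 as TPM and 739 with voom. With fewer genes tested at 5 FPKM, or a smaller pseudocount, these counts move by construction. As TPM and relative to recovered reads all genes were rescaled together, by a median of -0.24 and -0.19 on the log2 scale, which turns small rises into falls. That shift does not account for the 862 genes changed at least 2-fold as TPM, since relative to recovered reads there were 506. For that count and for the remaining settings the cause was not tested. Leaving out 1 library gave 1897 to 2495 genes higher, 1027 to 1529 lower and 431 to 452 changed at least 2-fold. There were 1897 higher and 1279 lower without shFAM49B replicate 2, 2124 and 1027 without shCON replicate 1, and 2342 and 1142 without shCON replicate 2. A lone library is then assumed to vary like the other group.

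Lists higher numbered 8 without a filter, 3 after quantile normalization and 0 with an estimated correlation (5 to 6 with 1 library left out), and lists lower 5 at 5 FPKM and 0 with an estimated correlation (6 to 9 with 1 library left out). The ERK output median was -0.30 at 5 FPKM, -0.25 after quantile normalization, -0.55 as TPM, -0.45 relative to recovered reads and -0.27 with an estimated correlation, none past the threshold, and -0.25 to -0.30 with 1 library left out. Across its alternatives the adjusted p ran from 0.00495 to 0.409.

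Medians changed sign as follows. Without a filter immediate early genes lay at -0.035, mesenchymal genes at -0.030 and embryonic kidney and neural markers at -0.013. At 5 FPKM receptors and ligands lay at 0.17 and NF-kB genes at 0.15. With median ratios over tested genes immediate early genes lay at -0.042. After quantile normalization immediate early genes lay at -0.046, ATF4 genes at -0.12, hypoxia genes at -0.00011, redox genes at -0.077 and heat shock genes at -0.076. As TPM immediate early genes lay at -0.21, RAC1 and WAVE genes at -0.075, mesenchymal genes at -0.17, redox genes at -0.11 and embryonic kidney markers at -0.083. Relative to recovered reads the same lists lay at -0.17, -0.050, -0.14, -0.091 and -0.050. Immediate early genes lay at -0.038 with the GC trend subtracted and ran from -0.074 to 0.10 with 1 library left out (-0.038 without shCON replicate 1, -0.074 without shFAM49B replicate 2). As TPM and relative to recovered reads genes shifted by a median of -0.24 and -0.19, which carries medians slightly above 0 below it. For other settings no cause was tested.

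The groups share replicate numbers, but same-numbered libraries did not deviate together across genes (correlation -0.013). The crossed value of 0.013 is the same value with its sign turned, which 2 libraries per group force. Whether same-numbered libraries shared a day or a culture cannot be told from this. With the replicate block 3429 genes were higher and 2036 lower, 443 changed at least 2-fold, 5 lists were higher and 8 lower, FAM49B stood at -2.06 and the ERK output median at -0.27. The block changed no call of a named gene or list.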

Other observations

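The tests of an epithelial programme within the same cells, of a fall in FAM49B without silencing, of scaling by recovered reads and of GC and length trends were chosen after the result was seen, as were the genes singled out here. Further markers of stratified epithelium, some of them keratins, fell as well. Of 35 such markers written down after the largest falls were known, 21 were tested, 18 fell and 3 did not pass. Of the 35, 7 also stand in lists fixed before the data were examined. The connexin GJB2 fell from 9.14 ± 0.0824 to 2.28 ± 0.511 FPKM, the desmosomal cadherin DSG3 from 3.74 ± 0.51 to 0.346 ± 0.112, TRIM29 from 3.97 ± 0.223 to 0.297 ± 0.0234 and the transcription factor KLF5 from 12.5 ± 0.441 to 4.52 ± 0.546. The desmosomal plaque genes DSP (36.8 ± 2.48 and 38.01 ± 1.26 FPKM) and JUP (63.4 ± 1.01 and 68.7 ± 0.853 FPKM) did not pass (limma adjusted p = 0.619 and 0.135). TP63, the master regulator of basal epithelium, stood at 6.07 and 5.08 FPKM in shCON and at 0.289 and 0.26 FPKM in shFAM49B.

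Of 14 further ovarian carcinoma markers, also listed afterwards, 5 were tested, and 2 rose, 1 fell and 2 did not pass. EMX2 rose by a log2 fold change of 0.62 and CD47 by 0.23, and MECOM fell by 0.36. PAX8 had 25 reads over the shCON libraries and 6 over the shFAM49B libraries, and WT1 had 206 and 105. The median of the 14 markers was low, at 0.242 and 0.373 FPKM in shCON and 0.0967 and 0.0691 FPKM in shFAM49B. The name OVCAR8 was taken as given, and the identity of the cells was not tested and stays open. By biotype, 34 of 85 tested small nucleolar RNAs were higher and 5 lower (median log2 fold change 0.76), 139 of 465 processed pseudogenes were higher and 38 lower, and 93 of 372 lincRNAs were lower and 25 higher (median -0.25). All small nuclear, nucleolar, Cajal body and micro RNAs together took 0.0173 ± 0.000948% of reads in shCON and 0.0213 ± 0.00128% in shFAM49B. The values of small nucleolar RNAs therefore rest on few reads. MT-RNR2, the large mitochondrial ribosomal RNA, rose by 1.63 on the log2 scale while 6 of the 13 mitochondrial protein genes fell.

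The fall of keratins and basal epithelial genes is the pattern most in need of follow-up. Scaling between libraries is argued against as its cause by size. The 4 scalings moved genes by a median of -0.015 to -0.24 on the log2 scale, whereas the keratins among the largest falls had log2 fold changes of -3.28 to -4.37. Of these keratins 6 of 6 stayed lower past the threshold under all 4 scalings. They were picked as the largest falls, so that count could hardly come out otherwise and is no further support. A candidate explanation is fewer cells of a second, stratified-epithelial type in the shFAM49B cultures. There were 32 further markers with at least 20 reads in a group. Their median log2 ratio of FPKM was -2.60 (6.07-fold lower, quartiles -3.30 and -1.10, 1 marker at its bound of 3 reads). KRT5, KRT17 and KRT6A, the most abundant keratins among the largest falls, fell 14.7-fold to 26.3-fold. They are part of the pattern to be explained and so are no further support for this explanation. Lower expression of an epithelial programme within the same cells after the knockdown predicts the same fall of 30 of the 32 markers in both libraries, and bulk libraries cannot tell these apart. FAM49B itself had a log2 ratio of -2.85, inside the range of these markers (-4.96 to 0.12), and 14 of the 32 fell at least as far. That range is wide, from BNC1 to the unchanged JUP, so a fall of almost any size would lie inside it and the comparison decides nothing. Loss of cells alone would also require that the remaining cells hold little FAM49B, which was not measured. Silencing of FAM49B and loss of cells that express it therefore cannot be told apart here.

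The breadth of small changes, 42.2% of tested genes, was weighed against sequence bias. Subtracting a trend on GC content within each library left 92.2% of the called genes with their call and sign, and subtracting a trend on gene length left 93.9%, which argues against either as the whole cause. The scaling by median ratios applied before deposit stays open as a cause of the split into rises and falls, since relative to recovered reads 1722 genes were higher and 4173 lower. An effect of the knockdown on many genes, a difference in cell makeup and a difference between cultures also stay open, as each group holds 2 libraries and no other knockdown was measured. Lists of histone, mitochondrially encoded and ribosomal protein genes were planned as signs of RNA quality or selection, which stays open too. Mitochondrial ribosomal RNA took 0.412% of reads in shCON and 1.08% in shFAM49B. Of 19 tested mitochondrial transfer RNAs, 10 were lower and 1 higher (median log2 fold change -1.38).

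Neighbouring genes around 7q32 (chromosome 7, 127652180 to 134066589) were among the larger rises: SND1 rose by 1.40, EXOC4 by 1.12 and ATP6V1F by 1.07 on the log2 scale. A difference in copy number or cell line makeup between the groups may shift neighbours together, and over 13183 windows of 25 neighbouring tested genes the most extreme median departed further than in any of 1000 shuffles of gene positions (permutation p = 0.001, the smallest they can give). The windows beyond 95% of shuffles (0.43) lay on chromosome 4 at 139436368 to 145938635 (-0.63) and 151102751 to 158908049 (-0.48) and on chromosome X at 74583088 to 92114461 (0.44). In that order, 16, 14 and 1 of the 25 genes were called lower and 1, 0 and 16 higher. A difference in copy number or cell line makeup stays open for these windows. The windows around 7q32 reached 0.34 to 0.35 and were not among them, so for these genes copy number cannot be told apart from other causes.

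Of 12 embryonic kidney and neural markers fixed before the data were examined, 3 (NEFL, NEFM and GATA3) had a mean of at least 5 FPKM. The bound set beforehand counted 3 or fewer as against cells of an embryonic kidney line as the main cells of all 4 libraries. The count lay at that bound and no such line was measured for comparison, so the count cannot exclude such cells.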
